A study of Mus musculus with 12 samples.

How the data were processed

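Gene expression was measured on mouse Illumina bead arrays in ear tissue of 2 inbred strains, LG/J and SM/J, taken from uninjured ear or from around an ear punch 7 days after injury. There were 12 arrays in 4 groups of 3. Per the labels, total RNA was extracted with Trizol, labelled with biotin and stained with streptavidin-Cy3, and the submitters' processing notes name BeadStudio without a version. The deposited value of each probe on each array is an average signal intensity on a linear scale. These per-array intensities showed no sign of normalization between arrays and no background subtraction, and covered 45281 probes each. A deposited table of the whole series holds intensities of 28845 of these probes after a between-array normalization that the authors do not describe. Its 12 column medians lay between 178.52 and 178.59, and each column kept the rank order of its own array (rank correlation 1). The filter behind that table is not stated. The files used here hold no detection p-values and no control probes.

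The analysis started from the per-array intensities. The plan fixed before the data were examined held the groups, the comparisons, the tests, the gene lists, the rule for naming genes and the alternatives, except for 3 alternatives named as added in the closing section. It named background correction from detection p-values (limma's neqc) and a filter on detection p. Neither could be run without these values, so the plan's rule for that case was used for the filter, and background was estimated from the signals themselves by the normexp model with an offset of 16, which was chosen after the files were read. Values were then put on the log2 scale and quantile normalized. The dimmest 25% of probes by mean level over the 12 arrays were removed, which left 33960. Of all probes, 23604 had 1 gene name in the table of names used, which covers the probes of the series table, 12 had several and 21665 had none. Each gene was represented by its probe with the highest mean level. Probes with no name or several names stayed separate features, giving 24690 features, of which 14218 were named genes and 10472 were not. Several families have closely related sequences (stefin A with its relatives, small proline-rich proteins, prolactin 2c, the H2-Q genes and beta globins), so which family member a probe reports is uncertain there. No probe sequences or positions were used.

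Differences were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 was used for estimated array weights), with 1 mean per group and 1 shared estimate of the spread (lmFit and eBayes). The 5 comparisons were day 7 against uninjured in LG/J, the same in SM/J, the difference between these 2 changes, LG/J against SM/J in uninjured ear, and LG/J against SM/J at day 7. P-values were adjusted by Benjamini and Hochberg over all features of a comparison, and a feature was called at an adjusted p under 0.05. Errors given with log2 changes are standard errors of the fit, with n = 3 arrays per group. The labels do not state that arrays come from separate animals, so p-values measure spread between samples. Replicate numbers were not used to pair arrays. Over the 10 pairs of arrays that share a number, correlations of their departures from the group mean ran from -0.093 to 0.186. An exact permutation test of 3 arrays against 3 cannot go below 0.10, so tests rest on the pooled spread of the fit.

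Genes were named by rule. For each injury comparison these were the 10 largest rises and the 10 largest falls among called features whose 3 day-7 arrays all lay beyond the 3 uninjured ones, and for each strain comparison the 8 largest each way by the same rule. For the difference of injury they were the 6 largest each way. From each list came up to 4 called members with the largest change, or the member with the lowest p where none was called. Cdkn1a, Mmp9, Tnc, Col1a1, Krt6a, Krt16, Mki67, Adipoq, Acan, Acta1, Tyr and the sex-linked genes were checks. No probe carried the names Mki67 or Tyr in that table. Some genes named as moving against their list were chosen after their values were seen, as the text states there.

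There were 26 lists with 985 members fixed, of which 803 were measured, and 25 lists were tested. Each was compared with all other features by limma's camera with a preset correlation of 0.01, adjusted over all 25 lists and 5 comparisons together. The same test was run with an estimated correlation, and fry tested whether a list's genes moved on balance one way. Calls of list members were also counted with p adjusted over the list alone. The sex-linked list, with 2 genes measured, was a check and was not tested.

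A background limit was set for each array from the lower side of its signal distribution, at the 95% quantile of a normal curve around the mode. This limit was chosen after the data were seen. It corresponded to 5.74 to 5.84 on the normalized log2 scale. Where all 3 arrays of 1 group lay below it, fold changes between 2 groups are given as lower bounds against it, and none is given where the other group did not exceed it. Called values of the difference of injury are fitted values, given beside values with signals under the limit set to it, and neither is a bound where uninjured ear lay below the limit in both strains. List medians are of fitted values. With signals under the limit set to it the neutrophil list had 1.02 in place of 1.41 in LG/J, wound keratinocytes 1.06 in place of 1.28, melanocytes -0.35 in place of -0.51 and Schwann cells -0.59 in place of -0.70. In SM/J Schwann cells had -0.58 in place of -0.81, wound keratinocytes 1.72 in place of 1.86, interferon response 0.77 in place of 0.90 and cartilage -0.36 in place of -0.48. The B cell list had 0.34 in place of 0.45 for the difference and the neutrophil list -0.62 in place of -0.72 between strains at day 7. Medians of other called lists moved by less than 0.1. Between 52.4% and 55.2% of probes lay above the limit on each array. The number of arrays limits the precision.

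The procedure was tested on simulated data built from the means and spreads of these features for the comparison of day 7 with uninjured ear in LG/J, over 24690 features. Of 67 features given a log2 change of 0.5, 4 were called (5.97%). At a change of 1, 50 of 67 were called (74.6%), and at 2, 65 of 66 (98.5%). Of 40 further features shifted together by 0.5 as a list, 5 were called. Among 24450 unchanged features 8 were called, which was 6.06% of all 132 calls, and 0 in a comparison with no change at all. The simulated noise was drawn independently for each feature, with no departure shared across an array and no normalization step. These rates therefore need not hold for the arrays themselves.

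The alternatives were no background correction, an offset of 50, median scaling, cyclic loess, no filter, the deposited series table, every probe as its own feature, only the groups compared, array weights, a variance prior with trend and robust settings, the replicate number as a block, and each array left out in turn. A filter on detection p and a block for chip or scan batch could not be run because the files give neither. A sex covariate was not run because the sex-linked genes did not split any group. Figures were drawn with matplotlib.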

Results

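The arrays measured transcript levels in ear tissue of LG/J and SM/J mice. LG/J mice close ear punch holes readily and SM/J mice do so poorly. Each strain gave 3 uninjured samples and 3 samples from around the punch at day 7. Median signal per array ran from 95.9 to 118 in intensity units, and 52.4% to 55.2% of probes lay above the background limit. In all, 24690 features were tested, of which 14218 were named genes.

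The component with the largest share of variance (47.3%) parted the strains, with 1 array between them. The next (27.3%) parted day 7 from uninjured ear. The array between was LG/J uninjured replicate 4, with a first-component score of 2.01 where the other LG/J uninjured arrays had -51.9 and -49.6. It lay with LG/J on 39 features that differed by over 3.5 on the log2 scale between strains at day 7. Its median position on them, from SM/J (0) to LG/J (1), was 1.0059, so the first component need not be strain alone. On this array the macrophage list differed from the other LG/J uninjured arrays by a median log2 value of -0.92, the mast cell list -1.01, the T cell list -0.56, the B cell list -0.60, the MHC list -0.54, the blood list -0.67, the melanocyte list -0.57, the contractile list -0.47 and the endothelial list -0.46. SM/J uninjured replicate 2 had a skeletal muscle list 1.25 higher than the other SM/J uninjured arrays. Xist, expressed from the inactive X chromosome, was high on all 12 arrays (11.6 to 13.2) and the Y-linked gene Uty was low (6.21 to 6.67), so the sex-linked genes did not split any group. The sex-linked list had a median change of -0.37 in LG/J and -0.06 in SM/J. Xist fell by 0.83 ± 0.24 in LG/J, a call lost on leaving out any 1 array other than LG/J uninjured replicates 1 and 3, with a change of -0.46 (adjusted p = 0.0652) without LG/J uninjured replicate 4.

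**Figure D1:**
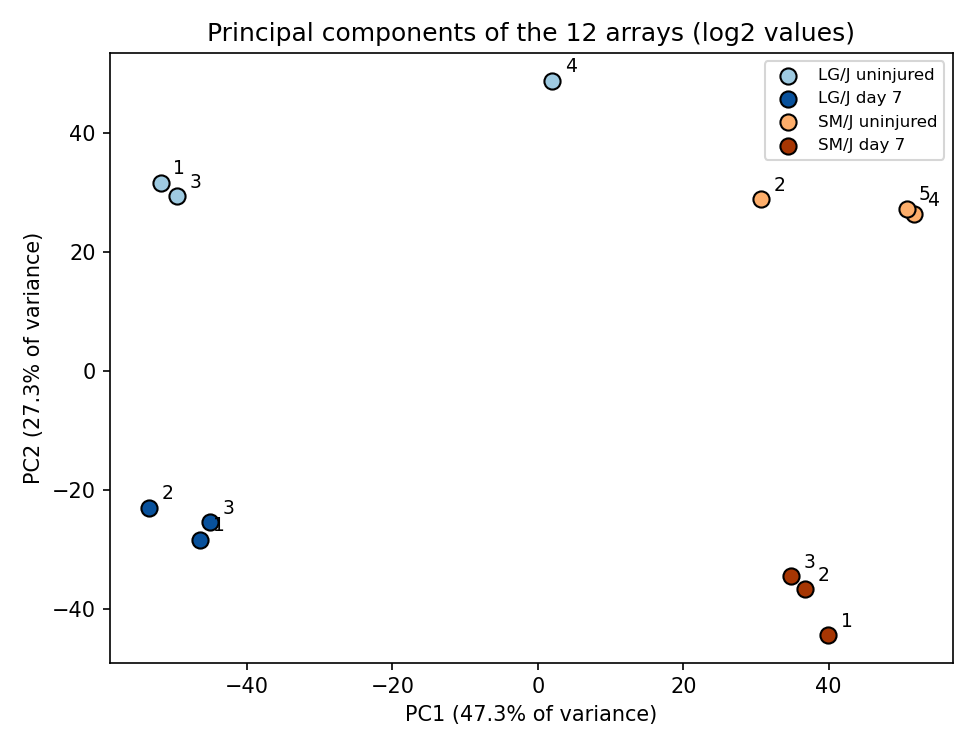
Scores of the 12 arrays on the first and second principal components of the log2 values, in percent of variance (47.3% and 27.3%), coloured by group with the replicate number beside each point. LG/J uninjured replicate 4 sits at 2.01 on the horizontal axis, between the strains, and the other LG/J arrays sit between -53.5 and -45.1.

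The comparison of day 7 with uninjured ear in LG/J asks which transcripts change around a wound in the strain that heals well. Krt16 and Krt6b, keratins of activated wound-edge keratinocytes, rose by 6.61 ± 0.23 and 5.55 ± 0.17 on the log2 scale (n = 3 arrays per group). Timp1, an inhibitor of matrix metalloproteases, rose by 3.23 ± 0.15, and the calcium-binding protein genes S100a8 and S100a9 of neutrophils and injured epidermis rose by 4.87 ± 0.25 and 3.92 ± 0.27. The falls were smaller. Myelin basic protein (Mbp) fell by 1.60 ± 0.14, the methyltransferase gene Inmt fell by 1.80 ± 0.28, and the muscle genes Cmya5, Myl10 and Mylk2 fell by 1.69 ± 0.38, 1.73 ± 0.25 and 1.58 ± 0.28. The stefin A relative Stfa1 had the largest rise (8.19 ± 0.47). Its relatives Cstdc5 and Stfa2 rose by 6.56 ± 0.28 and 6.35 ± 0.23 and Csta3 was at least 56.5-fold higher, but probes of this family do not reliably part its members. Sprr1b, Spink7 and Lce3f, genes of the epidermal barrier, rose by 5.69 ± 0.29, 5.19 ± 0.26 and 5.16 ± 0.18, and the antimicrobial lectin gene Reg3g was at least 17.2-fold higher.

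Immune lists rose in LG/J. Of 25 neutrophil and acute inflammation genes 14 rose and 1 fell (16 and 1 adjusted over the list alone), with a median change of 1.41 (camera adjusted p = 1.3e-14, adjusted p = 0.0699 with an estimated correlation). The 1 that fell was Camp, an antimicrobial granule peptide, at -0.69. Of 36 monocyte and macrophage genes 29 rose and 0 fell (31 and 0 adjusted over the list alone). The median was 1.37 (adjusted p = 3.5e-25, adjusted p = 0.233 with an estimated correlation). They included the chemokines Ccl4 (3.42 ± 0.44, and 1.57 by a second probe) and Ccl8 (2.71 ± 0.22) and the receptor Trem2 (2.49 ± 0.23). Interferon response genes rose in 18 of 40 (29 adjusted over the list alone). The median was 0.95 (adjusted p = 8.0e-12, adjusted p = 0.468 with an estimated correlation). Among them were Oas1g at 3.31 ± 0.45, Isg15 at 2.64 ± 0.44 and Oasl2 at 2.56 ± 0.51. The T cell list had 9 of 16 genes up (11 up and 1 down adjusted over the list alone). The median was 0.81 (adjusted p = 2.4e-05, adjusted p = 0.329 with an estimated correlation), and Ctla4, an inhibitory receptor, rose by 1.10 ± 0.23.

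Lymphocyte, mast cell and MHC values in LG/J depended in size on 1 uninjured array. The B cell and plasma cell list had 2 of 6 genes up (5 adjusted over the list alone). The median was 0.65 (adjusted p = 0.000573, adjusted p = 0.33 with an estimated correlation). The mast cell list had 4 of 11 up (5 adjusted over the list alone). The median was 0.70 (adjusted p = 0.00155, adjusted p = 0.5 with an estimated correlation). These included the high-affinity IgE receptor gene Fcer1a at 1.69 ± 0.15 and the tryptase gene Tpsab1 at 1.48 ± 0.29. MHC genes rose in 9 of 28 (13 up and 1 down adjusted over the list alone). The median was 0.56 (adjusted p = 4.3e-07, adjusted p = 0.359 with an estimated correlation). These included H2-M3 at 1.25 ± 0.24. Without LG/J uninjured replicate 4 the medians were 0.54 for T cells, 0.38 for B cells, 0.23 for mast cells and 0.33 for MHC, all still called.

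Epidermal and proliferation genes rose in LG/J as well. Of 39 wound keratinocyte genes 23 rose and 1, Krt8, a keratin of simple epithelia, fell by 0.91 (28 and 3 adjusted over the list alone). The median was 1.28 (adjusted p = 1.1e-20, adjusted p = 0.0541 with an estimated correlation). Of 44 cell cycle genes 26 rose and 0 fell (32 and 1 adjusted over the list alone). The median was 0.61 (adjusted p = 2.0e-18, adjusted p = 0.059 with an estimated correlation). The mitotic kinase gene Plk1 rose by 1.33 ± 0.14 and Birc5 (survivin) by 1.29 ± 0.14. Epidermal differentiation genes went both ways, 4 up and 3 down of 39 (4 and 4 adjusted over the list alone), with no shift of the list (median -0.00, adjusted p = 0.876): Krt1, an early differentiation keratin, rose by 3.17 ± 0.20 and Krt15, a basal and follicle stem cell keratin, fell by 1.45 ± 0.13. The hair follicle and sebaceous gland list, 2 up and 3 down of 35 (2 and 4 adjusted over the list alone), did not pass (median -0.25, adjusted p = 0.061). It was called lower without LG/J uninjured replicate 3 (-0.28) or 4 (-0.26) or LG/J day 7 replicate 1 or 2 (both -0.24), and under 7 of the other alternatives.

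Matrix and contractile genes rose in part. Of 45 fibrillar collagen and provisional matrix genes 16 rose and 3 fell (19 and 4 adjusted over the list alone). The median was 0.38 (adjusted p = 5.4e-07, adjusted p = 0.31 with an estimated correlation). The rises included Lrrc15, a marker of activated fibroblasts, by 4.29 ± 0.21, tenascin C (Tnc) by 2.75 ± 0.17 and Fbln2 by 2.01 ± 0.17, whereas Col1a1 did not pass (0.38 ± 0.28, adjusted p = 0.44). Contractile and myofibroblast genes rose in 11 of 19 (13 up and 1 down adjusted over the list alone). The median was 0.75 (adjusted p = 9.3e-09, adjusted p = 0.234 with an estimated correlation). These included smooth muscle actins Acta2 at 2.40 ± 0.21 and Actg2 at 2.32 ± 0.31. Of 29 matrix protease and inhibitor genes 12 rose and 2 fell (15 and 3 adjusted over the list alone). The median was 0.47 (adjusted p = 4.7e-08, adjusted p = 0.134 with an estimated correlation). These included Mmp13 at 3.65 ± 0.30, Adamts4 at 3.14 ± 0.18 and Mmp9 at 1.88 ± 0.23. A second Mmp13 probe changed by 0.16, so the size of its rise depends on the probe. Endothelial and angiogenesis genes rose in 11 of 37 (16 adjusted over the list alone). The median was 0.30 (adjusted p = 3.0e-06, adjusted p = 0.36 with an estimated correlation). These included Plvap at 1.27 ± 0.22.

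Lists of resident tissue fell in LG/J. Of 21 Schwann cell and nerve genes 10 fell and 1 rose (13 and 1 adjusted over the list alone). The median was -0.70 (adjusted p = 1.1e-07), the 1 list in LG/J that held with an estimated correlation (adjusted p = 0.0165). They included the myelin genes Pllp (-1.49 ± 0.14) and Ncmap (-1.25 ± 0.15), and the 1 that rose was Gap43, a gene of growing axons, at 0.68. Of 56 skeletal muscle genes 27 fell and 3 rose (39 and 4 adjusted over the list alone). The median was -0.98 (adjusted p = 1.3e-11, adjusted p = 0.5 with an estimated correlation). The 3 that rose were Tnnc1 (1.87 ± 0.34), Tnni1 (0.80) and Casq2 (1.09), which encode the slow troponins C and I and the cardiac form of calsequestrin. Adipocyte and lipid metabolism genes fell in 14 of 30 with 1 up, Angptl4 (20 and 1 adjusted over the list alone). The median was -0.55 (adjusted p = 1.9e-09, adjusted p = 0.059 with an estimated correlation), and the glucose transporter gene Slc2a4 changed by -1.07 ± 0.19. The melanocyte list had 2 of 16 down and 1 up (7 and 1 adjusted over the list alone) and a median of -0.51 (adjusted p = 0.00164, adjusted p = 0.359 with an estimated correlation), or -0.30 without LG/J uninjured replicate 1. Of 34 cartilage genes 12 fell and 5 rose (12 and 6 adjusted over the list alone). The median was -0.48 (adjusted p = 0.0271, adjusted p = 0.47 with an estimated correlation). Ucma fell by 1.41 ± 0.24 and Sox6 by 1.24 ± 0.24, whereas Chil1, a secreted chitinase-like protein also made by macrophages, rose by 2.27 ± 0.14 and Col9a3 by 1.56 ± 0.17. The cartilage call was lost without LG/J day 7 replicate 1 (median -0.35, adjusted p = 0.079), and the median was -0.17 without LG/J uninjured replicate 4.

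The remaining lists did not pass with camera in LG/J. Patterning and growth factor signalling had 5 up and 12 down of 75 (8 and 19 adjusted over the list alone; median -0.06, adjusted p = 0.372), with activin subunit Inhba up by 1.51 ± 0.15 and Fgf10 down (-1.11 ± 0.21). Hypoxia and glycolysis had 4 up and 1 down of 23 (adjusted p = 0.141, and 0.0213 with fry), oxidative phosphorylation 0 up and 3 down of 60 (adjusted p = 0.271), blood 0 of 15 either way (adjusted p = 0.137), and RNA quality and stress 2 up and 2 down of 22 (adjusted p = 0.318). The blood list was called higher without LG/J uninjured replicate 1 (0.35) or 3 (0.26). In total 2566 features were called in LG/J, 1343 up and 1223 down, of which 528 rose and 186 fell at least 2-fold. The day-7 arrays lay beyond all uninjured ones for 28.8% of features, where chance gives 10%. Without LG/J day 7 replicate 1 or LG/J day 7 replicate 3 the count was 1413 or 1599. The share of calls that rose was 52.3%, and 30.1% under median scaling.

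The same comparison in SM/J asks about the strain that heals poorly. Krt16 rose by 5.90 ± 0.23, Krt6b by 5.31 ± 0.17 and Timp1 by 3.62 ± 0.15 (n = 3 arrays per group). The inflammatory genes Saa3, an acute phase protein, S100a9, and Ccl4, a chemokine, rose by 5.54 ± 0.35, 5.50 ± 0.27 and 5.44 ± 0.44 (2.96 for a second Ccl4 probe). Genes of fat cells fell, among them leptin (Lep) by 2.39 ± 0.31 and the lipid droplet gene Cidec by 2.26 ± 0.34, and Mbp fell by 2.12 ± 0.14. The unnamed probe ILMN_1222219 had the largest rise (6.99 ± 0.12), and of stefin A relatives Stfa1 rose by 6.88 ± 0.47, Csta3 by 6.74 ± 0.38, Cstdc5 by 6.15 ± 0.28 and Stfa2 by 5.64 ± 0.23. Sprr2k was at least 24-fold higher. Other large falls were of Corin, a membrane protease, by 1.88 ± 0.16, Igsf1 by 1.84 ± 0.16 and the bone matrix gene Omd by 1.80 ± 0.28.

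Inflammatory and epidermal lists in SM/J included calls that held with an estimated correlation. Of 25 neutrophil and acute inflammation genes 19 rose and 0 fell (21 and 0 adjusted over the list alone). The median was 2.21 (adjusted p = 1.6e-25, adjusted p = 0.0273 with an estimated correlation). Of 39 wound keratinocyte genes 27 rose and 1, Krt8, fell by 1.16 (27 and 2 adjusted over the list alone). The median was 1.86 (adjusted p = 1.0e-28, adjusted p = 0.0273 with an estimated correlation). Of 36 monocyte and macrophage genes 23 rose and 0 fell (31 and 0 adjusted over the list alone). The median was 1.21 (adjusted p = 4.1e-25, adjusted p = 0.233 with an estimated correlation). These included Ccl8 at 3.54 ± 0.22, Ccl3 at 3.45 ± 0.33 and arginase 1 (Arg1) at 3.36 ± 0.18. Cell cycle genes rose in 27 of 44 (33 adjusted over the list alone). The median was 0.64 (adjusted p = 1.7e-20, adjusted p = 0.0541 with an estimated correlation). These included Birc5 at 1.60 ± 0.14. Matrix protease and inhibitor genes rose in 15 of 29 and fell in 3 (21 and 3 adjusted over the list alone). The median was 0.78 (adjusted p = 1.1e-12, adjusted p = 0.0541 with an estimated correlation). Mmp13 rose by 4.02 ± 0.30 (1.10 by a second probe), Mmp9 by 2.87 ± 0.23 and Mmp10 by 2.22 ± 0.25, and the metalloprotease inhibitor genes Timp2 and Timp3 were among those that fell (-0.63 and -1.03).

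Interferon response genes rose in 8 of 40 in SM/J (23 adjusted over the list alone). The median was 0.90 (adjusted p = 1.6e-09, adjusted p = 0.5 with an estimated correlation). Without SM/J day 7 replicate 1 the median was 0.42, and the rise of Oasl2, 2.25 ± 0.51 with all arrays, was 1.5. MHC genes had 0 up and 1 down of 28 (0 and 0 adjusted over the list alone). The median was 0.30 (adjusted p = 0.0225, adjusted p = 0.618 with an estimated correlation), and the call was lost without SM/J uninjured replicate 2 (0.21, adjusted p = 0.14) or SM/J day 7 replicate 1 (0.14, adjusted p = 0.12). Endothelial and angiogenesis genes had 7 up and 1 down of 37 (11 and 1 adjusted over the list alone). The median was 0.22 (adjusted p = 0.00775, adjusted p = 0.561 with an estimated correlation), and the call was lost under median scaling and the replicate block. T cell genes, 5 up and 1 down of 16, B cell genes, 1 up of 6, and mast cell genes, 2 up and 1 down of 11, did not pass as lists (adjusted p = 0.0618, 0.302 and 0.342), although Ctla4 rose by 1.33 ± 0.23, the costimulatory receptor Icos by 0.94 ± 0.19 and Fcer1a by 1.59 ± 0.15. The T cell list was called without LG/J uninjured replicate 3 (0.33, adjusted p = 0.0476) or SM/J day 7 replicate 3 (0.38, adjusted p = 0.028).

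Of 45 fibrillar collagen and provisional matrix genes in SM/J 13 rose and 6 fell (19 and 8 adjusted over the list alone). The median was 0.35 (adjusted p = 0.00196, adjusted p = 0.5 with an estimated correlation), a call lost without SM/J uninjured replicate 2 (0.25, adjusted p = 0.064). Lrrc15 rose by 3.43 ± 0.21, Tnc by 2.90 ± 0.17 and the matricellular gene Thbs2 by 1.84 ± 0.12. Contractile and myofibroblast genes had 5 up and 1 down of 19 (7 and 1 adjusted over the list alone). The median was 0.27 (adjusted p = 0.00193, adjusted p = 0.5 with an estimated correlation), or 0.42 without SM/J uninjured replicate 2, and Acta2 rose by 1.57 ± 0.21. Hypoxia and glycolysis genes rose in 6 of 23 with 1 down, Aldoc (6 and 1 adjusted over the list alone; median 0.16, adjusted p = 0.0163, adjusted p = 0.276 with an estimated correlation), a call lost under median scaling and without LG/J uninjured replicate 4 and SM/J uninjured replicate 2 together.

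Resident tissue lists fell in SM/J. Of 30 adipocyte and lipid metabolism genes 18 fell and 1, Angptl4, rose (27 and 1 adjusted over the list alone). The median was -0.73 (adjusted p = 9.9e-16, adjusted p = 0.0273 with an estimated correlation). Of 21 Schwann cell and nerve genes 12 fell and 1, Gap43, rose (13 and 1 adjusted over the list alone). The median was -0.81 (adjusted p = 2.1e-09, adjusted p = 0.0151 with an estimated correlation). Those that fell included S100b (-1.62 ± 0.16). Of 34 cartilage genes 14 fell and 5 rose (16 and 5 adjusted over the list alone). The median was -0.48 (adjusted p = 0.000739, adjusted p = 0.276 with an estimated correlation). Col9a1 (-1.62 ± 0.26) and Chad (-1.60 ± 0.22) fell, while Col9a3, Chil1, Col2a1, Trps1 and Matn2 rose by 1.55, 1.46, 1.18, 0.99 and 0.97. Of 75 patterning and growth factor signalling genes 23 fell and 4 rose (30 and 8 adjusted over the list alone). The median was -0.23 (adjusted p = 0.000503, adjusted p = 0.276 with an estimated correlation). Those that fell included the BMP antagonist gene Nog (-1.38 ± 0.22). Hair follicle and sebaceous gland genes fell in 6 of 35 with 2 up (7 and 2 adjusted over the list alone; median -0.25, adjusted p = 0.00702, adjusted p = 0.5 with an estimated correlation). The Wnt effector gene Lef1 was at least 1.58-fold lower. Melanocyte genes fell in 2 of 16 with 1 up (2 and 1 adjusted over the list alone; median -0.30, adjusted p = 0.00807, adjusted p = 0.467 with an estimated correlation).

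Of 56 skeletal muscle genes in SM/J 8 fell and 4 rose (15 and 4 adjusted over the list alone). The median was -0.51 (adjusted p = 0.000208, adjusted p = 0.696 with an estimated correlation). This call rested on SM/J uninjured replicate 2, without which the median was -0.12 (adjusted p = 0.37), while it was -0.82 without SM/J uninjured replicate 4 and -0.77 without SM/J uninjured replicate 5. The 4 that rose were Tnnc1 (2.78 ± 0.34), the fetal myosin gene Myh8 (1.66 ± 0.33), Casq2 (0.86) and Tnni1 (0.76). Epidermal differentiation (6 up and 2 down of 39, adjusted p = 0.496), blood (1 and 1 of 15, adjusted p = 0.487), oxidative phosphorylation (0 and 1 of 60, adjusted p = 0.621) and RNA quality and stress (6 and 1 of 22, adjusted p = 0.14) did not pass. Casq2, Tnni1, Trps1, Matn2, Timp2, Timp3, Gap43, Camp and Krt8 were chosen for naming after their values were seen. In total 2534 features were called in SM/J, 1397 up and 1137 down, of which 492 rose and 203 fell at least 2-fold, and 31.9% had groups apart. Leaving out 1 array gave 1532 (SM/J uninjured replicate 4), 1507 (SM/J uninjured replicate 5), 1454 (SM/J day 7 replicate 1), 1682 (SM/J day 7 replicate 2) and 4456 (LG/J uninjured replicate 4, through the shared spread). The share of calls that rose was 55.1%, and 27.7% under median scaling.

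The changes of both strains overlapped. Of the features that rose, 811 were called in both strains, where 76.0 would be shared if the calls were independent. Of those that fell, 549 were called in both (56.3 if independent), and 28 features were called in opposite directions. Both comparisons use the same spread estimate for each feature, so their calls are not independent even without a shared response. The correlation of the changes across 24690 features, which are not independent replicates, was 0.694 (Spearman's rho 0.502). Krt16, Krt6b, Timp1, Tnc, Lrrc15 and Mmp13 rose in both strains and Mbp, Pllp and Ncmap fell in both.

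**Figure D2:**
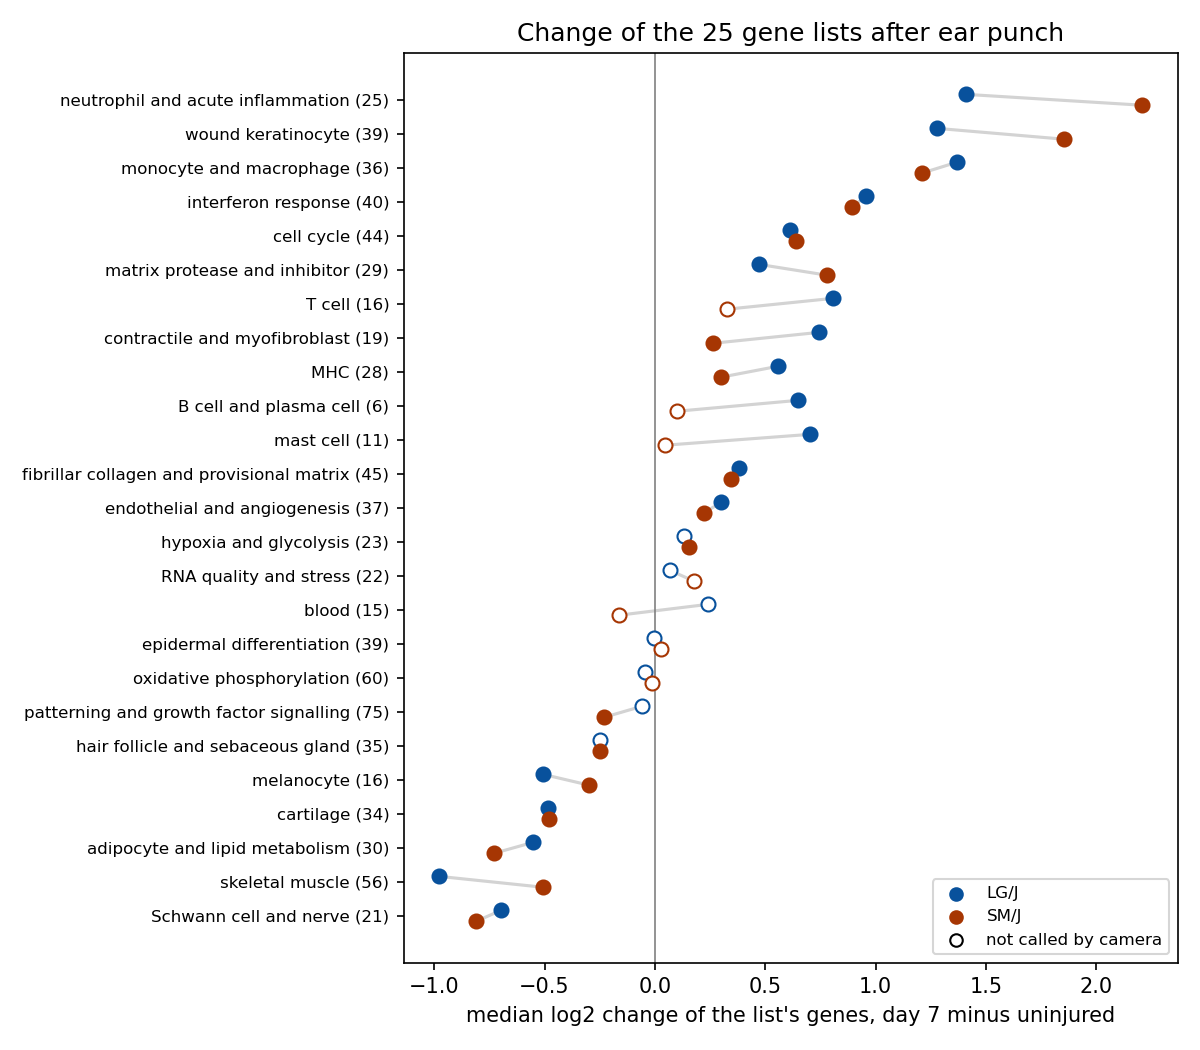
Median log2 change of each of the 25 gene lists (number of measured genes in parentheses) from uninjured ear to day 7, with LG/J in blue and SM/J in brown, filled where camera with a preset correlation called the list. The neutrophil list moved by 1.41 in LG/J and 2.21 in SM/J, and the Schwann cell list by -0.70 and -0.81.

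The difference between the injury changes, LG/J minus SM/J, asks which transcripts respond differently in the strains. Many of its genes lay under the background limit in uninjured ear, so each difference is given as fitted and, in a second value, with signals under the limit set to it. Gsdmc2, a gasdermin gene of epithelia, rose by 3.86 ± 0.32 in SM/J (1.72 by a second probe), while in LG/J it lay under the limit except on 1 array at day 7 (difference -3.49 ± 0.45 as fitted, adjusted p = 0.00574, and -3.79 at the limit). The proliferin genes Prl2c4 and Prl2c3 were at least 7.71-fold and 9.77-fold higher at day 7 in SM/J. In LG/J Prl2c4 passed the limit on 1 array at day 7 and Prl2c3 was at least 1.29-fold higher (differences -3.0 ± 0.33 and -2.79 ± 0.32 as fitted, -2.74 and -2.88 at the limit). The stefin relative Cstdc4 was at least 29.3-fold higher in SM/J and at least 2.60-fold in LG/J (-3.33 ± 0.41 as fitted, -3.49 at the limit). The unnamed probe ILMN_1252295 was at least 8.81-fold higher in SM/J and under the limit on all 6 LG/J arrays (-3.66 ± 0.30 as fitted, adjusted p = 0.000243, and -3.12 at the limit). These 5 kept their calls under every alternative run. Prl2c and stefin probes do not reliably part family members, and strain variants in the sequence under these probes were not analysed here.

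A further 12 named genes passed with all arrays and lost the call when single arrays were left out. With the replicate block 11 of them (all but Slc13a3) lost it too, as did 7 under median scaling and 6 under cyclic loess. Of those above the limit in all 4 groups and toward SM/J, Saa3 differed by -2.60 ± 0.49, the endotoxin co-receptor gene Cd14 by -2.08 ± 0.35 and Arg1 by -1.26 ± 0.25 (adjusted p = 0.049). Cxcl2, a neutrophil-attracting chemokine, was at least 14.3-fold higher at day 7 in SM/J. In LG/J the bound was 1.62-fold, and the change was not called (adjusted p = 0.0667). The Cxcl2 difference was -3.08 ± 0.59 as fitted (adjusted p = 0.0411) and -3.10 at the limit. The keratinocyte gene S100a7a was at least 5.64-fold higher in SM/J and 1.73-fold in LG/J (-1.52 ± 0.29 as fitted, -1.71 at the limit). Chil3 rose by 2.86 ± 0.28 in SM/J (difference -2.41 ± 0.40 as fitted, -2.63 at the limit). In LG/J it lay under the limit except on 1 array at day 7, and its change was not called (adjusted p = 0.361). Mcpt8, a protease of basophils, was at least 3.07-fold higher at day 7 in LG/J, and in SM/J it lay under the limit except on 1 array at day 7 (2.30 ± 0.36 as fitted, adjusted p = 0.0201, and 1.59 at the limit). The dicarboxylate transporter gene Slc13a3 rose by 2.33 ± 0.25 in LG/J with 0.25 ± 0.25 in SM/J (2.08 ± 0.35 as fitted, 2.14 at the limit). Positive differences were also called for Grm4 (1.41 ± 0.27) and Hbb-bs (1.13 ± 0.22), and for Prss46 (1.22 ± 0.21 as fitted, 0.93 at the limit) and Nptx2 (1.03 ± 0.20 and 1.09). Leaving out SM/J uninjured replicate 5 or SM/J day 7 replicate 1 ended all 12 calls, leaving out SM/J uninjured replicate 4 ended all but that of Chil3, and every other array except SM/J uninjured replicate 2 ended at least 2. Signs did not change: the fitted differences lay between -2.62 and -3.62 for Cxcl2, between -1.87 and -2.38 for Cd14, between -2.22 and -2.98 for Saa3, between -2.12 and -2.66 for Chil3, between -1.34 and -1.78 for S100a7a and between -1.08 and -1.39 for Arg1 over all 12 arrays left out in turn. For Mcpt8 they lay between 2.10 and 2.56, for Slc13a3 between 1.74 and 2.29, for Grm4 between 1.21 and 1.56, for Prss46 between 1.06 and 1.32, for Hbb-bs between 0.96 and 1.26, and for Nptx2 between 0.89 and 1.10.

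**Figure D3:**
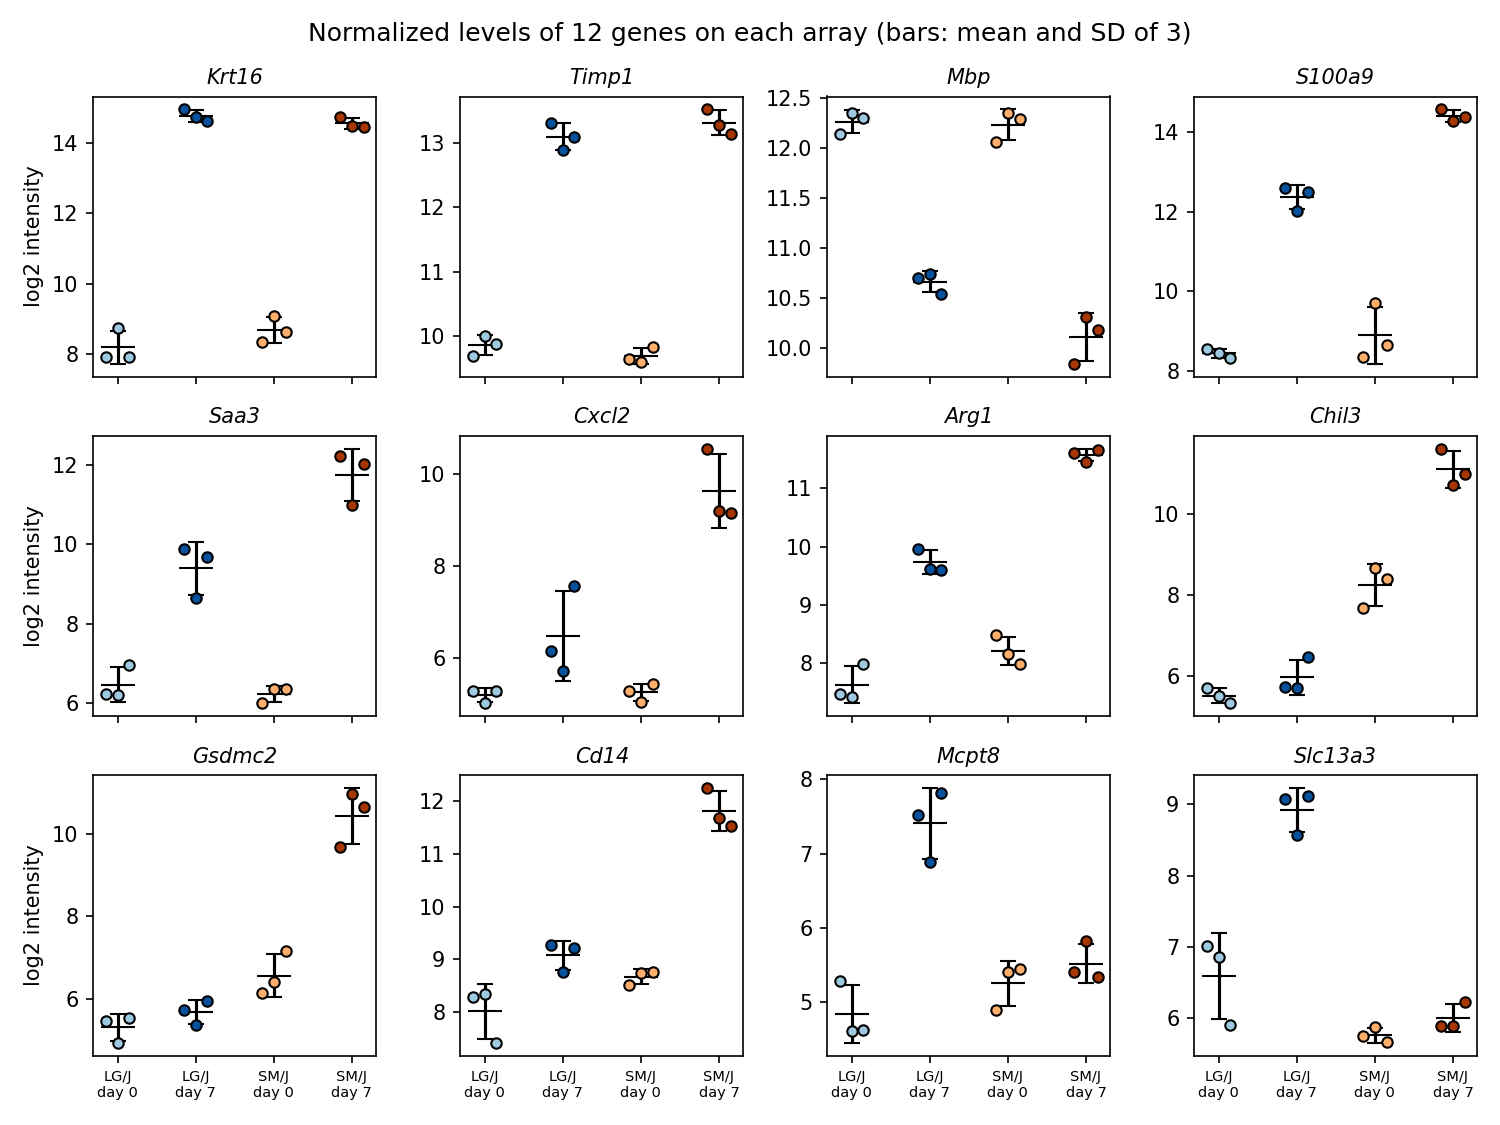
Normalized log2 intensity of 12 genes on each array (points), with the mean and standard deviation of each group of 3, for LG/J and SM/J at day 0 (uninjured) and day 7. Krt16, Timp1 and S100a9 rise in both strains and Mbp falls in both, Gsdmc2 rises from 6.57 to 10.4 in SM/J with 5.32 and 5.69 in LG/J, and Mcpt8 rises from 4.84 to 7.41 in LG/J with 5.25 and 5.52 in SM/J. Values under 5.74 are below the background limit on every array.

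Among lists, the neutrophil and acute inflammation list rose more in SM/J, with a median difference of -0.50 and 0 genes called higher and 2 lower of 25 (2 and 8 adjusted over the list alone; camera adjusted p = 1.1e-06, adjusted p = 0.276 with an estimated correlation). The wound keratinocyte list also rose more in SM/J (median -0.24, 0 and 1 of 39, 1 and 5 adjusted over the list alone; adjusted p = 0.000329, adjusted p = 0.467 with an estimated correlation), with -0.37 without LG/J day 7 replicate 1 and -0.15 without LG/J day 7 replicate 3. The contractile and myofibroblast list rose more in LG/J (median 0.47, 0 called of 19, 1 up adjusted over the list alone; adjusted p = 3.9e-05, adjusted p = 0.359 with an estimated correlation), with 0.31 without LG/J uninjured replicate 4. Patterning and growth factor signalling had a median difference of 0.17 (1 up of 75 adjusted over the list alone; adjusted p = 0.000739, adjusted p = 0.276 with an estimated correlation), or 0.26 without LG/J uninjured replicate 3. It was the 1 list that fry called in this comparison. The adipocyte list had 0.22 (adjusted p = 0.00311, adjusted p = 0.359 with an estimated correlation), or 0.35 without SM/J uninjured replicate 2, and the collagen and provisional matrix list 0.21 (3 and 2 of 45 adjusted over the list alone; adjusted p = 0.00393, adjusted p = 0.5 with an estimated correlation). Skeletal muscle had -0.36 (adjusted p = 7.8e-05, adjusted p = 0.673 with an estimated correlation), which ran from -0.79 without SM/J uninjured replicate 2 to -0.09 (adjusted p = 0.084) without SM/J uninjured replicate 4, with -0.22 without LG/J uninjured replicate 3 and -0.17 without SM/J uninjured replicate 5.

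Other list differences passed with all arrays and not without some of them. The T cell list had 0.39 (3 up of 16 adjusted over the list alone; adjusted p = 0.011, adjusted p = 0.5 with an estimated correlation), lost without LG/J uninjured replicate 4 (0.28, adjusted p = 0.054) or SM/J day 7 replicate 3 (0.31, adjusted p = 0.099). The B cell list had 0.45 (2 up of 6 adjusted over the list alone; adjusted p = 0.00914, adjusted p = 0.467 with an estimated correlation), lost without LG/J uninjured replicate 4 (0.29, adjusted p = 0.29). The mast cell list had a median difference of 0.21 (1 up of 11 adjusted over the list alone; adjusted p = 0.0148, adjusted p = 0.562 with an estimated correlation), lost without LG/J uninjured replicate 4 (0.04, adjusted p = 0.33) or SM/J uninjured replicate 4 (0.10, adjusted p = 0.09). It was 0.40 and 0.45 without LG/J uninjured replicates 1 and 3, 0.33 without SM/J day 7 replicate 2 and 0.34 without SM/J uninjured replicate 5. The MHC list had 0.27 (adjusted p = 0.00145, adjusted p = 0.51 with an estimated correlation), lost without LG/J uninjured replicate 4 (0.15, adjusted p = 0.25), with 0.17 without SM/J day 7 replicate 3. The endothelial list had 0.19 (adjusted p = 0.0251, adjusted p = 0.606 with an estimated correlation), lost without LG/J uninjured replicate 4 (0.04, adjusted p = 0.49), LG/J day 7 replicate 1 (0.18, adjusted p = 0.092) or SM/J day 7 replicate 1 (0.14, adjusted p = 0.075), and 0.33 without LG/J uninjured replicate 3. The matrix protease list had -0.18 (1 and 1 of 29 adjusted over the list alone; adjusted p = 0.0195, adjusted p = 0.5 with an estimated correlation), lost without SM/J uninjured replicate 2 (-0.06, adjusted p = 0.19), LG/J day 7 replicate 2 (-0.05, adjusted p = 0.082), LG/J uninjured replicate 1 (-0.17, adjusted p = 0.067) or LG/J uninjured replicate 3 (-0.19, adjusted p = 0.064). The blood list had 0.17 (1 up of 15, 2 and 1 adjusted over the list alone; adjusted p = 0.0358, adjusted p = 0.59 with an estimated correlation), lost without LG/J uninjured replicate 4 (0.05, adjusted p = 0.33), LG/J day 7 replicates 2 (adjusted p = 0.068) and 3 (adjusted p = 0.078), SM/J uninjured replicate 2 (adjusted p = 0.076) and SM/J day 7 replicates 1 (adjusted p = 0.065) and 2 (adjusted p = 0.08). It was 0.27 and 0.28 without LG/J uninjured replicates 1 and 3.

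The macrophage list was not called in the difference of injury (adjusted p = 0.51), and its median (0.16) and mean (-0.13) differed in sign. Arg1, Cd14 and Chil3 were its 3 members called, all toward SM/J (5 adjusted over the list alone), and without LG/J uninjured replicate 4 the list was called (-0.11, adjusted p = 0.0023). Interferon response, cell cycle, Schwann cell and cartilage lists did not pass, with medians of 0.13, -0.06, 0.15 and 0.17. Without SM/J day 7 replicate 1 the interferon response list was called, with a median of 0.61 (adjusted p = 3.1e-16). It was called also under median scaling (0.12, adjusted p = 0.0474) and the replicate block (0.28, adjusted p = 0.045). The cartilage list was called without LG/J uninjured replicate 4 (0.21), LG/J day 7 replicate 1 (0.26), SM/J uninjured replicate 4 (0.19) or SM/J day 7 replicate 2 (0.23), and the hair follicle list without LG/J uninjured replicate 1 (0.19). In total 105 features were called, 13 toward LG/J and 92 toward SM/J, of which 11 and 90 differed at least 2-fold, and 2181 had an unadjusted p under 0.05. The lean toward SM/J was not seen when LG/J uninjured replicate 4 and SM/J uninjured replicate 2 were left out together (613 toward LG/J and 632 toward SM/J). It was seen without either of them alone (22 against 103 and 46 against 306) and with array weights (243 against 593). The count was 352 without SM/J uninjured replicate 2, and lower without others: 62, 44, 21, 26, 36, 19, 14, 21, 29 and 43 without LG/J uninjured replicates 1 and 3, LG/J day 7 replicates 1, 2 and 3, SM/J uninjured replicates 4 and 5, and SM/J day 7 replicates 1, 2 and 3.

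The comparison of strains in uninjured ear asks what differs before a wound. Genes higher in LG/J included the type II collagen gene Col2a1 at 3.32 ± 0.18, the Wnt antagonist gene Frzb at 3.56 ± 0.16, and the slow myosin light chain genes Myl3 and Myl2 at 3.81 ± 0.31 and 3.65 ± 0.48 (n = 3 arrays per group). Immune genes lower in LG/J were the T cell genes Trat1 (-2.90 ± 0.17) and Cd3g (-2.45 ± 0.31), S100a8 (-2.52 ± 0.25), the chemokine gene Ccl2 (-1.74 ± 0.22) and Chil3, at least 5.50-fold lower. H2-K1, a class I MHC gene, was 2.47 ± 0.23 higher in LG/J and H2-Q7 lower (-2.40 ± 0.29), the latter from a family of closely related sequences. The tryptase gene Tpsab1 was 2.41 ± 0.29 higher.

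The largest differences between strains are given here as read by 1 probe of each gene. Calm5 was at least 99-fold lower in LG/J, Sspn at least 59.9-fold, Me1 at least 59.4-fold, and Cbwd1, Zfp979 and 1110059E24Rik at least 18.2-fold, 17.7-fold and 20.3-fold. Krtdap (7.25 ± 0.78), Emb (7.08 ± 0.26), Csrp1 (5.08 ± 0.18) and Reep3 (4.65 ± 0.26) were higher in LG/J, Car13 was at least 58.9-fold higher and Ptprb at least 19.3-fold, and Ctsc was lower (-4.66 ± 0.21). A strain difference in the sequence under a probe would give such values too, and probe sequences were not used here. Across 5999 genes with 2 probes, the changes read by both probes correlated at 0.418 for the strain difference in uninjured ear, against 0.722 and 0.713 for injury in LG/J and SM/J. Within LG/J the correlation was 0.435 for uninjured replicate 4 minus replicates 1 and 3. Within SM/J it was 0.364 for uninjured replicate 2 minus replicates 4 and 5. A low correlation therefore does not by itself point to sequence variants. Of 1779 genes whose first probe was called between strains, the second was called in the opposite direction for 90 (5.06%), against 2 of 898 (0.223%) for injury in LG/J.

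Few lists differed in uninjured ear. Of 56 skeletal muscle genes 26 were higher in LG/J and 0 lower (33 and 0 adjusted over the list alone). The median was 0.78 (adjusted p = 1.4e-07, adjusted p = 0.562 with an estimated correlation). These included the sarcolipin gene Sln at 2.68 ± 0.38 and Tnnc1 at 2.67 ± 0.34. Of 36 macrophage genes 10 were lower in LG/J and 1 higher (15 and 1 adjusted over the list alone). The median was -0.54 (adjusted p = 3.7e-07, adjusted p = 0.5 with an estimated correlation), or -0.28 without LG/J uninjured replicate 4 (adjusted p = 0.018). Melanocyte genes were higher in 6 of 16 and lower in 1 (7 and 1 adjusted over the list alone; median 0.39, adjusted p = 0.00784, adjusted p = 0.467 with an estimated correlation). These included Dct (1.20 ± 0.21), Pmel (1.37 ± 0.28) and Oca2 (1.10 ± 0.19), for which LG/J uninjured replicate 4 lay nearer to SM/J. The T cell list was called lower (4 of 16 lower, 5 adjusted over the list alone; adjusted p = 0.0475, adjusted p = 0.562 with an estimated correlation) with a mean of -0.53 but a median of 0.04, and the call was lost without LG/J uninjured replicate 4 (median 0.17, adjusted p = 0.27), SM/J uninjured replicate 2 (-0.05, adjusted p = 0.0621), LG/J day 7 replicate 2 (adjusted p = 0.0562) or SM/J day 7 replicates 1, 2 or 3 (adjusted p = 0.0534, 0.0526 and 0.0508), and kept without LG/J uninjured replicate 3 (-0.17). RNA quality and stress genes were lower in 7 of 22 and higher in 3 (8 and 3 adjusted over the list alone; median -0.21, adjusted p = 0.0359, adjusted p = 0.5 with an estimated correlation), lost without LG/J uninjured replicate 4 (-0.06, adjusted p = 0.19) or SM/J uninjured replicate 2 (-0.07, adjusted p = 0.072), with -0.09 without LG/J uninjured replicate 3.

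The other 20 lists did not pass with camera in uninjured ear. Cartilage had 4 higher and 4 lower of 34 (median 0.13, adjusted p = 0.86, and 0.0295 with fry). MHC had 9 higher and 3 lower of 28 (adjusted p = 0.372), epidermal differentiation 10 and 5 of 39, oxidative phosphorylation 6 and 13 of 60 (adjusted p = 0.181), and neutrophil and acute inflammation 5 and 3 of 25. Lists called without 1 array were B cells (0.68 without LG/J uninjured replicate 4), collagen and provisional matrix (-0.02 without LG/J uninjured replicate 3 and -0.13 without SM/J uninjured replicate 2) and wound keratinocytes (-0.06 without LG/J day 7 replicate 1 and -0.11 without SM/J uninjured replicate 5). In total 4887 features were called, 2845 higher in LG/J and 2042 lower, of which 536 and 746 differed at least 2-fold, and 28.7% had groups apart. Without 1 array the count was 8176 (LG/J uninjured replicate 4), 2761 (LG/J uninjured replicate 1), 2723 (LG/J uninjured replicate 3), 2521 (SM/J uninjured replicate 4) and 2658 (SM/J uninjured replicate 5). The share higher in LG/J was 58.2%, and 47.8% under cyclic loess. Median scaling moved the median of all features to 0.10, from 0.07.

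The comparison of strains at day 7 asks what differs around the wound. Inflammatory genes lower in LG/J included Chil3 at -5.15 ± 0.28, the interleukin gene Il1b at -3.35 ± 0.43, Cxcl2 at -3.14 ± 0.41, Cd14 at -2.74 ± 0.25 and Ccl4 at -2.67 ± 0.44 (n = 3 arrays per group). Lilrb4a, an inhibitory receptor of myeloid cells, was at least 15.9-fold lower. The contractile genes Actg2 (1.62 ± 0.31), Myl9 (1.34 ± 0.22) and Tagln (1.23 ± 0.15) were higher in LG/J. So were Tpsab1 (3.92 ± 0.29), the B cell kinase gene Blk (1.69 ± 0.24), Lep (1.83 ± 0.31), Frzb (2.91 ± 0.16) and Col2a1 (2.68 ± 0.18). Of the 115 genes named in this comparison that passed the background limit on some uninjured array, 55 had LG/J uninjured replicate 4 nearer to the SM/J uninjured mean, among them Actg2, Myl9, Tagln, Blk and Lep, and over all 5769 such called features this held for 3119 (54.1%).

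Of 25 neutrophil and acute inflammation genes at day 7, 13 were lower in LG/J and 3 higher (14 and 4 adjusted over the list alone). The median was -0.72 (adjusted p = 3.0e-05, adjusted p = 0.359 with an estimated correlation). These included Retnlg (-2.25 ± 0.38) and Saa3 (-2.36 ± 0.35). Of 36 macrophage genes 15 were lower and 0 higher (15 and 1 adjusted over the list alone). The median was -0.32 (adjusted p = 7.0e-06, adjusted p = 0.538 with an estimated correlation), or -0.20 and -0.21 without LG/J day 7 replicate 2 and SM/J day 7 replicate 1, and 0.01 under median scaling, where the list was still called. Of 39 wound keratinocyte genes 14 were lower and 3 higher (14 and 3 adjusted over the list alone). The median was -0.39 (adjusted p = 4.5e-05, adjusted p = 0.362 with an estimated correlation), or -0.23 without LG/J day 7 replicate 3, including the protease inhibitor genes Serpinb2 (-2.40 ± 0.54) and Slpi (-2.05 ± 0.28) and the keratin gene Krt6a (-1.60 ± 0.29). Contractile genes were higher in 9 of 19 and lower in 1 (10 and 1 adjusted over the list alone; median 0.62, adjusted p = 0.00197, adjusted p = 0.5 with an estimated correlation). B cell genes were higher in 4 of 6 (5 adjusted over the list alone; median 0.76, adjusted p = 0.00162, adjusted p = 0.359 with an estimated correlation). Cd22 was at least 1.70-fold higher. MHC genes were higher in 12 of 28 and lower in 3 (12 and 3 adjusted over the list alone; median 0.35, adjusted p = 0.0086, adjusted p = 0.562 with an estimated correlation), a call lost with the series table, with only its probes and with the probe-gap covariate.

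Skeletal muscle genes were higher in LG/J at day 7 in 11 of 56 (11 adjusted over the list alone; median 0.39, adjusted p = 0.0118, adjusted p = 0.82 with an estimated correlation), lost without LG/J day 7 replicate 3 (adjusted p = 0.056). Hair follicle genes were higher in 7 of 35 and lower in 1 (7 and 1 adjusted over the list alone; median 0.33, adjusted p = 0.0322, adjusted p = 0.562 with an estimated correlation), lost without LG/J day 7 replicate 1 (adjusted p = 0.062) or SM/J day 7 replicate 1 (adjusted p = 0.053). Melanocyte genes were higher in 6 of 16 and lower in 1 (6 and 1 adjusted over the list alone; median 0.40, adjusted p = 0.0372, adjusted p = 0.506 with an estimated correlation), lost without LG/J day 7 replicate 1 (adjusted p = 0.052) or SM/J day 7 replicate 2 (adjusted p = 0.0503). RNA quality and stress genes were lower in 7 of 22 and higher in 3 (10 and 3 adjusted over the list alone; median -0.28, adjusted p = 0.0151, adjusted p = 0.468 with an estimated correlation), lost without LG/J day 7 replicate 1 (adjusted p = 0.054), with -0.47 without LG/J day 7 replicate 3. The other 15 lists did not pass with camera. Of these, fry called Schwann cell (median 0.26, adjusted p = 0.00207), cartilage (0.20, adjusted p = 0.0031), adipocyte (0.23, adjusted p = 0.0133) and patterning lists (0.15, adjusted p = 0.0314). The interferon response list, with a median of 0.38 (adjusted p = 0.514), was called higher in LG/J without SM/J day 7 replicate 1 (0.72, adjusted p = 1.5e-06). Matrix proteases were called lower without LG/J uninjured replicate 3 (-0.22), LG/J day 7 replicate 1 (-0.32) or SM/J day 7 replicate 1 (-0.19), and under 6 of the other alternatives. Adipocytes were called without SM/J uninjured replicate 2 (0.23), cartilage without LG/J day 7 replicate 1 (0.23) and oxidative phosphorylation without SM/J day 7 replicate 3 (-0.10).

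At single probes Teddm3 (5.15), Emb (6.22 ± 0.26) and Csrp1 (5.45 ± 0.18) were higher in LG/J at day 7, and Calm5 at least 89.8-fold lower. Second probes gave like values for Krtdap (4.85 and 6.73), Ctsc (-4.90 and -4.75) and Chil3 (-5.15 and -4.79), and for Zfp979, at least 20-fold lower with -4.23 at the second. They did not for Mettl14 (at least 15.6-fold higher, with -0.61 at the second), Cptp (at least 17.4-fold lower, with 1.39), 1110059E24Rik (at least 25.8-fold lower, with -0.10) and Adamts9 (3.51 and -0.23). The correlation between both probes was 0.450 over 5999 genes. In total 6083 features were called, 3491 higher in LG/J and 2592 lower, of which 625 and 923 differed at least 2-fold, and 47.4% had groups apart. Without LG/J day 7 replicate 2 or SM/J day 7 replicate 1 the count was 3597 or 3608, and median scaling moved the median of all features to 0.11 from 0.08. Between uninjured ear and day 7 the strain calls overlapped, with 1877 features higher in LG/J in both (402 if independent), 1436 lower in both (214 if independent) and 38 opposite. These comparisons also share the spread estimate of each feature, so their calls are not independent.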

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

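The tests of tissue or label exchange and of immune cell content for LG/J uninjured replicate 4 were chosen after the result was seen. So was the test of the RNA state at the large strain differences, and so were the intervals required of each test. The other tests were set before. Intervals printed beside medians in this section come from resampling features or genes on the same arrays. Features and genes are not independent replicates, and these printed intervals hold no spread between arrays or animals.

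The change from uninjured ear to day 7 differed between strains, by the test of the difference itself, for 17 of the features picked by the naming rule, out of 105 called. The values are as fitted, and uninjured ear lay below the background limit in both strains for ILMN_1252295, Cstdc4, Cxcl2, Prl2c4, Prl2c3, S100a7a, Mcpt8, Prss46 and Nptx2. Toward a larger rise in SM/J these were ILMN_1252295 (-3.66), Gsdmc2 (-3.49), Cstdc4 (-3.33), Cxcl2 (-3.08), Prl2c4 (-3.0), Prl2c3 (-2.79), Saa3 (-2.60), Chil3 (-2.41), Cd14 (-2.08), S100a7a (-1.52) and Arg1 (-1.26). Toward LG/J they were Mcpt8 (2.30), Slc13a3 (2.08), Grm4 (1.41), Prss46 (1.22), Hbb-bs (1.13) and Nptx2 (1.03). For Grm4 and Hbb-bs the difference came with a fall in SM/J (-1.23 and -0.81). The same test on lists gave median differences of -0.50 (neutrophil and acute inflammation), -0.36 (skeletal muscle), -0.24 (wound keratinocyte), -0.18 (matrix protease and inhibitor), 0.17 (patterning and growth factor signalling), 0.17 (blood), 0.19 (endothelial), 0.21 (mast cell), 0.21 (fibrillar collagen and provisional matrix), 0.22 (adipocyte), 0.27 (MHC), 0.39 (T cell), 0.45 (B cell and plasma cell) and 0.47 (contractile and myofibroblast), with 0 of these lists called under an estimated correlation. Dixon's test of single arrays lying apart was not made for groups of 3.

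Regrouping gave the following. For the difference of injury, 5 of 100 relabellings of strain within day (drawn of 200, the real one included) gave at least as many calls as the real 105, with up to 543 in the others. Relabelling mixes the strains within a group, so strain differences enter the spread and lower the calls. The share is therefore not a chance rate, and chance cannot be excluded for this count. The 4 others all set LG/J uninjured replicates 1 and 3 with SM/J uninjured replicate 2, but of the 10 drawn with that grouping 2 gave fewer calls (68 and 87) and 4 gave 0. The count of 543 points to a structure of the samples, which this grouping alone does not give. For each of the other 4 comparisons 10 splits of 6 arrays exist and 1, the real one, gave as many calls, which is too few for a share under 0.05. The real and highest other counts were 2566 and 3 for injury in LG/J, 2534 and 0 for injury in SM/J, 4887 and 1787 for strain in uninjured ear (the split that exchanges LG/J uninjured replicate 4 with SM/J uninjured replicate 2), and 6083 and 0 for strain at day 7.

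LG/J uninjured replicate 4 lay apart from the other LG/J uninjured arrays, toward SM/J. An exchange with SM/J tissue is argued against on 39 features that part the strains by over 3.5 on the log2 scale. The median position of this array on them, from SM/J (0) to LG/J (1), was 1.0059 (95% interval over features 0.957 to 1.03). Fewer immune cells in that piece of ear stays open: 62 of 69 members of the macrophage, T cell, B cell and mast cell lists were lower (median -0.794), but these lists were already seen to be low on this array, and 5 of 18 lists of other tissues (blood, melanocyte, contractile, endothelial and hair follicle) also lay in the lowest 2.5% of random lists. A state of the RNA or its labelling that acts on single probes stays open, because the correlation of both probes of a gene was 0.435, against 0.713 for injury in SM/J, between the bounds set for either answer. With 1 uninjured array against 2 day-7 arrays, injury in SM/J gave 0.634. For SM/J uninjured replicate 2 minus replicates 4 and 5 the correlation was 0.364, so a low value was not particular to LG/J uninjured replicate 4. The biological difference between animals is untested.

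Single features differed over 8-fold between the strains at day 7. The RNA state of LG/J uninjured replicate 4 is argued against here for 64 such features. The median position of that array on them was 0.979 (95% interval over features 0.928 to 1.01), that of an LG/J array. This position rests on that array alone. On features with smaller strain differences at day 7 the array lay closer to SM/J. Its median position was 0.40 for differences of 0.5 to 1 on the log2 scale, 0.41 for 1 to 2 and 0.55 for 2 to 3. For those features the RNA state stays open. A sequence variant under the probe could give differences over 8-fold, and so could a transcript level that differs. In the 17 genes with a second probe the median ratio of the second difference to the first was 0.637 (95% interval 0.0205 to 0.953), with 9 ratios over 0.5 and 5 under 0.25, so these cannot be told apart for the group. The number of genes with a second probe keeps it open.

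The neutrophil and acute inflammation list rose more in SM/J by camera with a preset correlation, a call not held with an estimated correlation or fry. LG/J uninjured replicate 4 as its only source is argued against for the genes of the list. Without that array their median difference was -0.683 (95% interval over genes -1.02 to -0.398). A state of the RNA shared with other arrays stays open. A score of the gaps between both probes of a gene was 0.45 and 0.48 on SM/J uninjured replicates 4 and 5. It was 0.18 to 0.22 on SM/J day 7 arrays. More neutrophils in the SM/J wound could account for it. In that case the 11 measured neutrophil genes, mostly of receptors and granules, would differ by -0.5 or less. Their median was -0.499 with 9 of 11 lower (-0.486 with signals under the background limit set to it), just short of that bound. These genes belong to the list itself, so their median is not independent of it. None was called for the difference (adjusted p from 0.0961 for S100a9 to 0.806 for Csf3r). Camp and Il1r2 counted as lower through falls in LG/J (-0.69 and -0.48), with -0.19 and -0.007 in SM/J. S100a8 (1.01) and Cxcr2 (0.30) went the other way, so a change in the cells' state, which was not tested, stays open too.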

How the results depend on the processing

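The 3 alternatives added after seeing the data were leaving out LG/J uninjured replicate 4 and SM/J uninjured replicate 2 together, only the probes of the series table, and a covariate for the gap between both probes of a gene. This covariate was built along the difference of LG/J uninjured replicate 4 from replicates 1 and 3. On all other arrays it parted the strains, so it is confounded with strain. Among genes picked by the naming rule no call reversed under any alternative in which the gene was measured, and no called list did by the direction of its test. Other called genes were not checked for this. List medians changed sign 11 times where a list was called, 7 of them for T cells in uninjured ear (from 0.04, down to -0.26 with the probe-gap covariate). The others were the macrophage list at day 7 under median scaling (0.01 from -0.32, still called), the macrophage difference without LG/J uninjured replicate 4 (-0.11 from 0.16), the blood difference without both arrays (-0.01 from 0.17) and T cells at day 7 with the probe-gap covariate (-0.09 from 0.07). Of called features picked by the naming rule, mostly for large changes, 76 of 107 kept the call in every alternative for injury in LG/J, 66 of 98 in SM/J, 5 of 17 for the difference, 64 of 113 for strain in uninjured ear and 81 of 117 at day 7. Median scaling weakened 39 named results and the replicate block 76. Signal over background limits the low end, since 52.4% to 55.2% of probes lay above the limit. A detection filter, a chip or scan batch and a sex covariate were not run, and only the groups compared is the full fit for the difference.

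Counts of called features outside 1.5 times the value with all settings as planned were as follows, and the cause was not tested except where fewer arrays enter. For injury in LG/J they were 1567 with only the groups compared and 4344 with array weights, and 1413 to 2754 with 1 array left out. For injury in SM/J they were 5692 with array weights, 1243 with the replicate block, 5076 without both arrays, 4167 with the probe-gap covariate, and 1454 to 4456 with 1 array left out. For the difference they were 836, 10, 1245 and 334 in the same order, and 14 to 352. For strain in uninjured ear they were 10007, 2336, 8748 and 2559 in the same order, 2208 with only the groups compared, and 2521 to 8176. For strain at day 7 they were 9142 with array weights, 2459 with the covariate, and 3597 to 8327.

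Lists called numbered 1 in LG/J, 4 in SM/J and 0 in the other 3 comparisons with an estimated correlation. With fry they were 11 in SM/J, 1 for the difference and 3 for strain in uninjured ear. For the difference they were 8 with array weights and 8 without both arrays. For strain in uninjured ear they were 3 without background correction, 3 with the series table and 3 with only its probes.

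Calls of single lists by camera with a preset correlation were lost as follows under other processing or models, beside those lost without 1 array that the report names, and the cause was not tested. In LG/J, cartilage and melanocyte calls were lost with the series table and with only its probes, and cartilage also without both arrays. In SM/J they were endothelial (median scaling, replicate block), MHC (these 2, the series table, only its probes, without both arrays), hypoxia (median scaling, without both arrays), muscle (array weights, without both arrays), collagen (without both arrays), melanocyte (the series table, only its probes) and hair follicle (only its probes). For the difference, T cell, B cell, mast cell, MHC, endothelial, blood and matrix protease calls were lost with array weights and without both arrays. B cell and endothelial calls were lost also with the series table and only its probes, blood and protease calls also under median scaling, and the protease call under cyclic loess. The collagen call was lost with every probe as its own feature and the adipocyte call with the replicate block. For strain in uninjured ear, T cell and RNA quality calls were lost without background correction, with the series table, only its probes, array weights, and without both arrays. T cells were lost also with an offset of 50 and with only the groups compared, RNA quality also under median scaling and with every probe, and melanocytes with every probe. At day 7, hair follicle, MHC and RNA quality calls were lost with the series table and only its probes. Hair follicle, MHC and melanocyte calls were lost with the probe-gap covariate, hair follicle also without background correction, with an offset of 50 and without both arrays. Melanocyte and RNA quality calls were lost with every probe, and RNA quality under median scaling.

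Lists not called as planned gained a call by the same test as follows, beside those without 1 array, and the cause was not tested. In LG/J these were hair follicle (no background correction, cyclic loess, no filter, array weights, replicate block, without both arrays, probe-gap covariate) and blood (every probe). In SM/J they were T cell (no filter), mast cell (every probe) and blood (replicate block). For the difference they were cartilage (array weights, without both arrays, covariate) and interferon response (median scaling, replicate block). For strain in uninjured ear they were B cell (no filter, every probe, array weights, without both arrays), blood (every probe, covariate), wound keratinocyte (cyclic loess, replicate block), neutrophil (replicate block), mast cell (covariate), hair follicle (no filter), and collagen and oxidative phosphorylation (every probe). At day 7 they were matrix protease (no background correction, offset of 50, no filter, every probe, replicate block, covariate), adipocyte (median scaling, no filter, every probe, covariate), oxidative phosphorylation (no background correction, cyclic loess, every probe, covariate), cartilage (no filter, covariate), T cell (covariate) and endothelial (every probe).

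With fry, which does not compare a list with other genes, 31 list calls were lost and 7 gained, and with an estimated correlation 60 were lost and 0 gained. Lost with fry were cartilage, skeletal muscle and interferon response in LG/J, and contractile, hair follicle, skeletal muscle, endothelial, melanocyte, interferon response and MHC in SM/J. For the difference all called lists but patterning were lost, among them neutrophil (adjusted p = 0.0606), contractile (0.111) and wound keratinocyte (0.168). Macrophage, T cell, skeletal muscle and RNA quality were lost in uninjured ear, and macrophage, hair follicle, skeletal muscle and RNA quality at day 7. Gained were hypoxia in LG/J, cartilage and hypoxia in uninjured ear, and cartilage, adipocyte, Schwann cell and patterning at day 7.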

Other observations

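The probe-gap score and the positions given in this part were chosen after the data were seen.

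Reading both probes of a gene gave an array-level value beside the comparisons. The score built from gaps between the probes lay between -0.58 and -0.36 on LG/J arrays other than uninjured replicate 4, at 0.48 on that array, and between 0.12 and 0.48 on SM/J arrays. It was built along the difference of LG/J uninjured replicate 4 from replicates 1 and 3. The distance between these arrays on the score was therefore set by construction. The position of LG/J uninjured replicate 4 between SM/J (0) and LG/J (1) had a median of 0.40 on features differing by 0.5 to 1 on the log2 scale between the strains at day 7, 0.55 for 2 to 3, 0.92 for 3 to 3.5, and 1.01 above.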
